A study of Mus musculus with 10 samples.

How the data were processed

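Expression was measured by RNA sequencing in 10 mouse libraries of 4 groups: 3 libraries each of Col2+ and Col10+ rib chondrocytes and 2 each of Runx2_cHet_KO and Runx2_cHom_KO calvarial osteoblasts. Per the labels' protocols, chondrocyte libraries were made from 100 ng of total RNA with a TruSeq kit, and osteoblast libraries from 1.7 ng with the SMARTer Stranded Total RNA-Seq Pico kit. Reads were processed with TopHat2 2.1.0, Cufflinks and Cuffdiff 2.2.1 against the mouse build mm9, per the submitters' processing notes, which give these names without their order. The deposited values are FPKM computed by the authors: a group value for each chondrocyte sort and a value for each osteoblast library, per the file headers. The way in which replicates were combined into the group values is not given in the sources used here. The chondrocyte table held 1 further column of values that matched no sample, and it was not used. Neither table gives coordinates, so positions are not reported.

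FPKM is relative to the mapped fragments of a library and to transcript length, so a few very abundant rows lower all others. The 20 most abundant rows held 26.5% of the summed FPKM in the Col2+ sort, 50.8% in the Col10+ sort and between 39.7% and 42.0% in the osteoblast libraries. Rows with no gene name numbered 3444 in the chondrocyte table and held 8.48% of its Col2+ and 17.0% of its Col10+ total. These rows, and 25 chondrocyte and 26 osteoblast rows whose gene names had become calendar dates, were left out. Rows naming several genes were tested but not counted as members of a list. In the chondrocytes 21992 of 22583 distinct names, and in the osteoblasts 22116 of 22645, matched a symbol or synonym in reference gene tables of build GRCm38, which were used for names only. Where a symbol had several rows, the row with the highest mean was used. A value of exactly 0 can be a failed estimate: Hmgcs1, a gene of cholesterol synthesis that cells in general use, was listed at 0 in all 4 osteoblast libraries and in Col10+ cells, so such values are described as listed at 0 and no fold is given against them.

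Depth was unknown, since neither table holds counts. Rows under 0.06 FPKM in a pair of osteoblast libraries (146 to 226 rows per pair) showed a preferred ratio of values, taken as the relative worth of 1 read; the chondrocyte group values did not allow this. No counting interval was computed.

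All tests used log2(FPKM + 1), which understates the change of low genes. In the chondrocytes a gene was counted as higher or lower in Col10+ cells where this value differed by at least 1 (2-fold) and the higher sort had 5 FPKM or more; without replicates no test was made. In the osteoblasts limma 3.58.1 in R 4.3.3 was fitted with trended and robust variances to genes at 1 FPKM or more in at least 2 libraries, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in size, Runx2_cHom_KO minus Runx2_cHet_KO. Standard errors are limma's. Runx2, Col2a1 and Col10a1 also had a two-sided exact permutation test over the osteoblast libraries.

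A total of 28 gene lists were fixed before the data were examined: columnar and resting chondrocyte matrix, chondrogenic transcription factors, prehypertrophic and hypertrophic chondrocyte, osteoblast, osteocyte, mineralisation and phosphate handling, Runx family and partner, cranial mesenchyme transcription factors, hedgehog, Wnt, BMP and TGF-beta and FGF signalling, matrix proteases and inhibitors, cell cycle, glycolysis and hypoxia response, secretory pathway and unfolded protein response, cholesterol synthesis, and markers of fibroblast, tendon and perichondrium, endothelial, erythroid, macrophage and monocyte, osteoclast, neutrophil, skeletal muscle, neural and Schwann, epithelial and adipocyte cells, and immediate early and dissociation stress genes. Lists share members, such as Spp1, Alpl and Dmp1. In the chondrocytes a list's median log2 change over members at 1 FPKM or more was placed among 10000 random lists of equal size matched on mean expression in 20 bins, as a percentile that describes these values. In the osteoblasts lists of at least 3 members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation. The estimated setting also takes its degrees of freedom from the few libraries, so a call lost there has no single cause. Overlaps of the comparisons were set beside the product of the list sizes divided by the number of genes in both tables.

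The genes named were chosen by a rule set before the data were examined: Runx2, Col2a1 and Col10a1; the 10 largest rises and 10 largest falls among changed genes, leaving out microRNAs, small nucleolar and small nuclear RNAs, predicted genes, accessions and rows of several genes; up to 4 changed members of each list, and up to 4 others where fewer than 2 changed; and the 5 genes of each overlap with the largest smaller change. Some genes that this rule takes are not reported here. Tested on simulated data for 11661 osteoblast genes, the limma step recovered 96% of 100 genes changed by 1.5 and 98% of 100 changed by 3 on the log2 scale, with 8 unchanged genes called. The camera step called 2.5% of 200 unchanged simulated sets and 100% of 50 shifted by 1, and the percentile step 0% of 50 unchanged lists and 100% of 50 shifted by 2. The simulated osteoblast genes varied independently, and those changed for the limma step had a mean log2 value above 3. The camera figures therefore do not cover lists whose genes vary together, such as the macrophage list with an estimated correlation of 0.986.

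Alternatives set before the data were examined were other pseudocounts (0.1 and 5), no filter or a minimum of 10 FPKM, limits of 1.5-fold and 4-fold, columns centred on the median ratio, equal totals without the 20 most abundant rows, summed rows of a symbol, the replicate number as a block, quantile normalization, each osteoblast library left out in turn, an estimated correlation and random lists not matched on expression. After the data had been seen, leaving out libraries was extended to named genes, lists and overlaps, and the block to named genes and lists. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.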

Results

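RNA was sequenced from mouse skeletal cells in 10 libraries that fall into 4 groups. Rib chondrocytes from mice of the ICR strain at postnatal day 1 were sorted by fluorescent reporters into cells with the Col2a1 reporter (Col2+) and cells with the Col10a1 reporter (Col10+), with 3 libraries for each sort. Col2a1 encodes the main collagen of cartilage and Col10a1 the collagen of hypertrophic chondrocytes, the enlarged cells next to forming bone. Osteoblasts, the bone-forming cells, came from the calvaria (skull roof) of C57BL/6 embryos at E17.5. They carried the genotypes Runx2_cHet_KO or Runx2_cHom_KO, with 2 libraries each. Runx2 is a transcription factor required for osteoblast formation. The genotype names read as heterozygous and homozygous conditional knockouts, which the labels do not spell out.

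The values were FPKM (fragments scaled to the length of the transcript and to all mapped fragments of the library). The chondrocyte table held 1 value per gene for each sort, so no chondrocyte difference has a replicate check, an error or a p-value. The osteoblast table held a value for each library, and its errors are given as ± SD over n = 2 libraries. Total depth was unknown in both tables. FPKM steps of rarely read genes gave relative depths for the osteoblast libraries. There 1 read in Runx2_cHet_KO library 1 was worth 0.830 times a read in Runx2_cHet_KO library 2, 0.794 times a read in Runx2_cHom_KO library 1 and 0.844 times a read in Runx2_cHom_KO library 2. Runx2_cHet_KO library 1 was therefore the deepest of the 4. Summed FPKM was 567147 in the Col2+ sort, 712295 in the Col10+ sort and between 536770 and 567272 in the osteoblast libraries.

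The gene named in the genotypes was measured first. Runx2 was at 43.4 and 53.9 FPKM in the Runx2_cHet_KO libraries and at 32.9 and 32.6 FPKM in the Runx2_cHom_KO libraries. The change of -0.55 on the log2(FPKM + 1) scale, with a standard error of 0.13, did not pass the test (limma adjusted p = 0.0707), although both Runx2_cHom_KO libraries lay below both Runx2_cHet_KO libraries. The two-sided exact permutation p was 0.333, the smallest that 2 libraries against 2 allow. A gene-level FPKM does not show whether particular exons were deleted, so this level neither establishes nor excludes the deletion. In the rib sorts Col10a1 was at 59.5 FPKM in Col2+ cells and 2895 FPKM in Col10+ cells, 48.7-fold higher. Col2a1 was at 44205 and 31532 FPKM, 1.40-fold lower in Col10+ cells, and Runx2 was at 6.06 and 9.93 FPKM, 1.64-fold higher in Col10+ cells and under the 2-fold limit.

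The first comparison asked how the Col10+ rib sort differs from the Col2+ rib sort. The Col10+ sort had far higher levels of some genes of hypertrophic cartilage and bone matrix. Ibsp, a mineral-binding matrix protein, was at 0.047 and 235 FPKM, Alpl, the phosphatase that drives mineral deposition, at 0.971 and 137 FPKM, and Col1a1, the main collagen of bone, at 10.6 and 3305 FPKM (Col2+ value first, as in all pairs here). It had lower levels of Sox9, the master transcription factor of chondrocytes (595 and 103 FPKM, 5.77-fold lower), and of Cytl1, a secreted cartilage protein (836 and 40.6 FPKM, 20.6-fold lower). Genes of neutrophils, macrophages and red cells were also far higher in the Col10+ sort, with S100a9 at 0.041 and 1929 FPKM and Lyz2 at 0.083 and 657 FPKM. Of 8354 genes at 5 FPKM or more in either sort, 1150 were higher and 1188 lower in Col10+ cells by at least 2-fold on the log2(FPKM + 1) scale. The median change over these genes was -0.31 on the log2 scale, and 0.05 with the columns centred on the median ratio. The split was then 1552 higher and 606 lower, and 71.9% of the changed genes were higher in place of 49.2%.

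**Figure D1:**
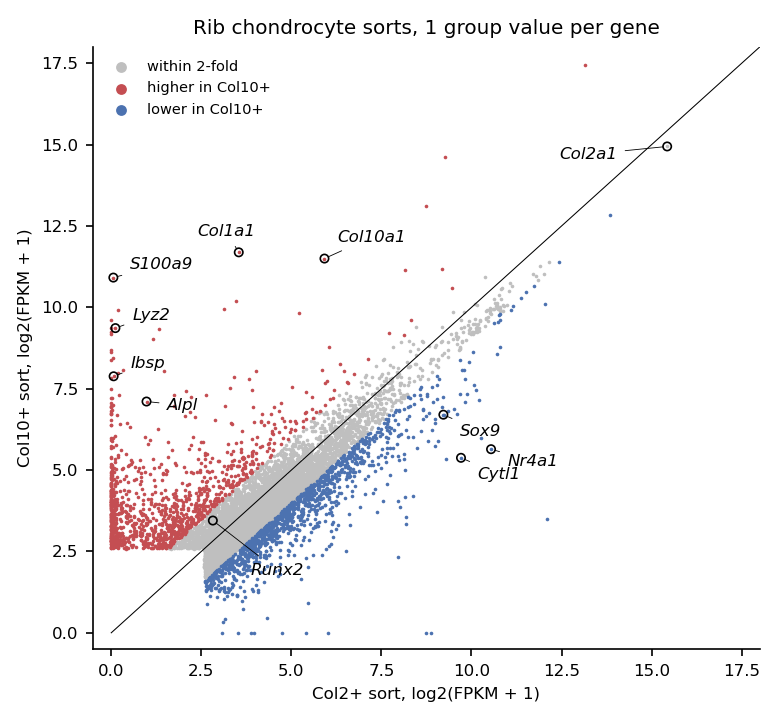
Expression in the Col2+ sort (x axis) and the Col10+ sort (y axis) of rib chondrocytes, as log2(FPKM + 1) with 1 group value per gene; each point is 1 of 8354 genes, the line marks equal values, and colours mark genes at least 2-fold higher (1150, red) or lower (1188, blue) in Col10+ cells. Col10a1, Col1a1, Ibsp and Alpl lie far above the line together with the blood-cell genes S100a9 and Lyz2, and Sox9, Nr4a1 and Cytl1 lie below it.

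Genes of late chondrocytes and bone formed the first group. In the list of prehypertrophic and hypertrophic chondrocyte genes, 12 of 20 measured members were higher and 3 lower, with a median log2 change of 1.69 at percentile 100 of 10000 random lists matched on expression. Besides Ibsp, Alpl and Col10a1, the collagenase Mmp13 was at 0.424 and 78.4 FPKM. The lower members, named after their values were seen, were Spp1 (3400 and 1614 FPKM, log2 change -1.07), Vegfa and Fgfr1. In the osteoblast list 13 of 24 members were higher and 3 lower (median 2.28, percentile 100). Bglap, which encodes osteocalcin, was listed at 0 in Col2+ cells and was at 21.7 FPKM in Col10+ cells, a value that its near-identical neighbour Bglap2 makes uncertain. In the osteocyte list 4 of 9 members were higher and 0 lower (median 1.61, percentile 99.96; over members at 10 FPKM or more 0.94, percentile 92.3). Among them were Irx5 (0.19 and 12 FPKM), Phex (0.066 and 9.02 FPKM) and Dmp1 (24.4 and 111 FPKM, 4.56-fold). The mineralisation list was split, with 6 of 13 members higher and 6 lower (median -0.06, or 0.19 with centred columns, percentile 89.1; over members at 10 FPKM or more -1.15, percentile 0.58). Slc37a2 was 22.0-fold higher, while Enpp1 and Ank, which supply the mineral inhibitor pyrophosphate, were lower (507 and 86.8 FPKM, and 732 and 117 FPKM). The higher osteoblast genes stood beside higher endothelial, osteoclast and blood-cell genes in the same sort, described below.

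Among cartilage genes of the earlier stages more were lower than higher. Of 19 measured members of the columnar and resting matrix list, 7 were lower and 1 higher (median -0.84, or -0.49 with centred columns, percentile 4.765, or 0.03 among random lists not matched on expression). Among the lower ones Col9a2, Lect1, Epyc and Prg4, named after their values were seen, had log2 changes of -1.03, -1.02, -1.08 and -1.05. These lie just past the limit, by less than the shift of the list median on centring. Ucma was 4.43-fold lower (1673 and 377 FPKM), Fmod 4.07-fold lower (1770 and 435 FPKM), and Matn1 5.56-fold higher (22.0 and 122 FPKM). Of 12 chondrogenic transcription factors, 6 were lower and 1 higher (median -0.98, percentile 0.01). Sox5, a partner of Sox9, was 4.16-fold lower (24.3 and 5.85 FPKM) and Wwp2 3.08-fold lower (198 and 64.4 FPKM), while Arid5b was 4.68-fold higher (1.48 and 6.93 FPKM). In the Runx list, Runx1 was 3.02-fold lower (21.3 and 7.05 FPKM) and Runx3 3.68-fold higher (1.39 and 5.13 FPKM), with 1 of 4 members each way (median -0.16, or 0.17 with centred columns, percentile 57.25). The cranial mesenchyme list had 2 of 6 members lower and 0 higher (median -0.62, or -0.32 with centred columns, percentile 9.51), Foxc1 2.64-fold and Alx1 2.38-fold. Alx1 was under the 2-fold limit with centred columns.

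Genes of FGF signalling and immediate early genes were lower in Col10+ cells. In the FGF list 9 of 11 members were lower and 1 higher (median -1.93, percentile 0). The feedback inhibitor Spry2 was 8.83-fold lower (201 and 22.8 FPKM), the ligands Fgf18 and Fgf2 10.6-fold and 4.91-fold lower, and the receptor Fgfr1 5.31-fold lower (385 and 72.5 FPKM). Immediate early and dissociation-stress genes, which respond within minutes to signals and to cell isolation, were lower in 10 of 12 cases and higher in 2 (median -2.51, percentile 0). Nr4a1 was at 1491 and 48.9 FPKM, Fosb at 329 and 17.3 FPKM, Egr1 at 1125 and 176 FPKM and Dnajb1 at 278 and 39.6 FPKM. The higher members, the heat shock genes Hspa1a (21.9 and 85.0 FPKM) and Hspa1b, were chosen after their values were seen. The related receptors Nr4a3 and Nr4a2 were 61.8-fold and 31.4-fold lower, and Egr4, Hbegf, Rcan1, Chac1 and Dusp14 were 49.8-fold, 26.7-fold, 19.5-fold, 19-fold and 19.1-fold lower. With Cytl1, Nr4a1 and Fosb these made up the 10 largest differences downwards on the log2 scale.

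The other signalling lists and the secretory list lay within the middle 95% of random lists, except that the Wnt list lay below it over members at 10 FPKM or more (median -1.04, percentile 0.59). In the hedgehog list 1 of 11 members was higher and 1 lower (median -0.36, or -0.06 with centred columns, percentile 19.3). Ihh, the ligand made by prehypertrophic chondrocytes, was at 1.52 and 32.9 FPKM, and the co-receptor Boc was 4.28-fold lower. In the Wnt list 2 of 20 members were higher and 5 lower (median -0.10, or 0.23 with centred columns, percentile 42.6). Wnt10b was at 0.144 and 5.53 FPKM, and Sfrp1, Lef1 and Wif1 were 6.94-fold, 4.49-fold and 3.34-fold lower. In the BMP and TGF-beta list 0 of 21 members were higher and 4 lower (median -0.50, or -0.16 with centred columns, percentile 11.1). They were Gdf5, Bmp4, Bmpr1b and Bmpr1a, of which the last 2 were under the 2-fold limit with centred columns. The secretory list had 1 of 19 members higher and 5 lower (median -0.29, or 0.05 with centred columns, percentile 86.3). Sdf2l1 was 7.04-fold higher, and the stress regulators Atf4 (896 and 223 FPKM), Ddit3 (169 and 35.2 FPKM) and Herpud1 (302 and 63.8 FPKM) were lower.

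More genes of the cell cycle and of glycolysis were higher than lower in the Col10+ sort, in which the neutrophil, macrophage, erythroid and osteoclast lists had medians of 7.08, 6.95, 4.48 and 2.39. In the cell cycle list 13 of 22 members were higher and 0 lower (median 1.57, percentile 100; over members at 10 FPKM or more 1.24, percentile 94.3). Mki67 was at 0.878 and 18 FPKM, Top2a at 1.63 and 15.8 FPKM, Birc5 at 1.36 and 14.6 FPKM and Ccnb2 at 0.833 and 11.6 FPKM. In the glycolysis and hypoxia list 9 of 19 members were higher and 2 lower (median 0.97, percentile 100). The higher ones included Egln3, Ankrd37, Adm and the enzyme Pfkl, which was 5.07-fold higher. Vegfa, named after its values were seen, was among the lower ones (181 and 49.5 FPKM). In the cholesterol synthesis list 0 of 14 members passed the 2-fold limit (median 0.20, or 0.53 with centred columns, percentile 99.3, or 89.7 among random lists not matched on expression). Nsdhl was 2.01-fold higher in FPKM and passed the limit with centred columns, Dhcr7 was 1.44-fold and Insig1 1.31-fold higher. The matrix protease list had 4 of 12 members higher and 4 lower (median 0.30, or 0.64 with centred columns, percentile 99.2, or 92.9 among random lists not matched on expression). Mmp9 was at 0.359 and 87.0 FPKM, Adamts4 at 0.056 and 6.73 FPKM and Ctsk at 17.3 and 104 FPKM, and Mmp9 and Ctsk are also on the osteoclast list. Over members at 10 FPKM or more the protease median was -0.52 at percentile 49.3.

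Markers of blood cells and osteoclasts were higher in the Col10+ sort. All 8 measured neutrophil genes were higher (median 7.08, percentile 100). S100a8 was at 0.145 and 971 FPKM, Ngp at 0.042 and 344 FPKM, and Camp was listed at 0 and at 148 FPKM. Of 12 macrophage genes 11 were higher (median 6.95, percentile 100). Tyrobp and C1qc were listed at 0 in Col2+ cells and were at 334 and 134 FPKM in Col10+ cells, and Ctss was at 0.021 and 148 FPKM. All 3 measured erythroid genes, among them Alas2 and Slc4a1, were higher (median 4.48, percentile 99.98), and the haemoglobin row Beta-s was at 1.52 and 650 FPKM. Retnlg, listed at 0 and at 396 FPKM, and Stfa2l1, at 0.13 and 252 FPKM, completed the 10 largest differences upwards. Of 8 osteoclast genes, markers of the bone-resorbing cells, 5 were higher and 0 lower (median 2.39, percentile 100), such as Acp5 (2.38 and 156 FPKM) and Atp6v0d2 (0.244 and 15.3 FPKM).

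Vessel, fat and connective tissue genes followed. Of 9 endothelial genes 7 were higher and 0 lower (median 3.11, percentile 100). Cdh5 and Emcn were listed at 0 in Col2+ cells and were at 22.8 and 13.4 FPKM in Col10+ cells, Pecam1 was at 0.084 and 21.9 FPKM, and Tie1 at 0.063 and 9.31 FPKM. Of 5 adipocyte genes 3 were higher and 0 lower (median 1.46, percentile 99.8), with Fabp4 15.5-fold higher (7.99 and 124 FPKM), Lpl at 0.404 and 35 FPKM and Cebpa 3.00-fold higher. In the fibroblast, tendon and perichondrium list 3 of 12 members were higher and 2 lower (median 0.70, percentile 99.5). Postn was 12.6-fold higher (14 and 176 FPKM), Thbs4 was at 0.897 and 29.8 FPKM, Dpt at 0.02 and 6.82 FPKM, and Dcn was 2.41-fold lower, which was under the 2-fold limit with centred columns. Muscle genes had 2 of 5 members higher and 0 lower (median 1.20, percentile 95.8, or 98.1 among random lists not matched on expression; Tnnt3 2.51-fold, Acta1 5.63-fold), and neural and Schwann genes 2 of 5 higher and 0 lower (median 1.0, percentile 94.1), among them the myelin gene Mbp. Of 3 epithelial genes 2 were lower and 0 higher (median -1.5, percentile 0.065), Krt18 7.07-fold and Epcam 3.36-fold. Of the 28 lists, 14 lay in the highest 2.5% of random lists and 4 in the lowest 2.5%. The osteocyte, cell cycle and protease lists left the highest 2.5% over members at 10 FPKM or more, and the protease and cholesterol lists did so among random lists not matched on expression.

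**Figure D2:**
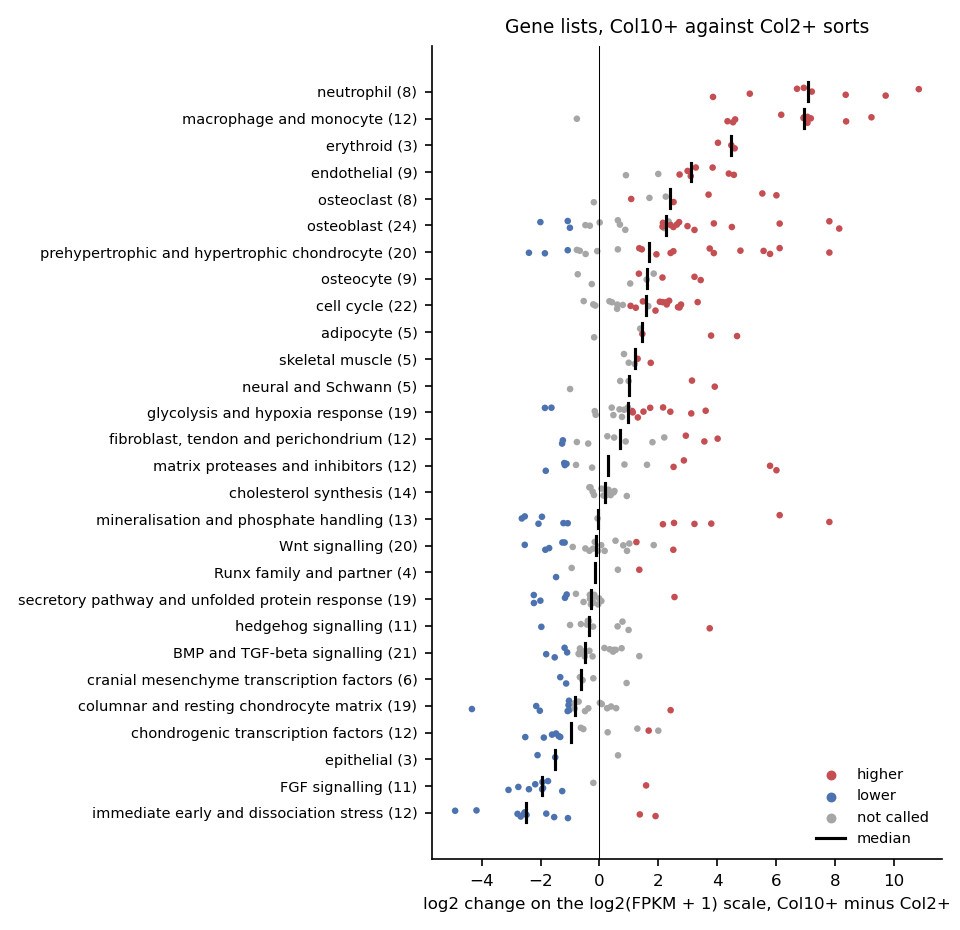
Log2 change (x axis, log2(FPKM + 1) scale, Col10+ minus Col2+) of each member of 28 gene lists (y axis, with the number of members at 1 FPKM or more in either sort); points are genes, coloured where at least 2-fold higher (red) or lower (blue) with 5 FPKM or more, and black bars are list medians. The neutrophil and macrophage medians of 7.08 and 6.95 are the highest, and the medians of FGF signalling (-1.93) and of immediate early genes (-2.51) the lowest.

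The second comparison asked how calvarial osteoblasts of the Runx2_cHom_KO genotype differ from those of the Runx2_cHet_KO genotype. Some genes of bone matrix fell, while the most abundant ones did not pass the test. Spp1, which encodes osteopontin, fell from 413 ± 68.3 to 81.2 ± 13.6 FPKM (SD, n = 2 in each group here and below). Dmp1, a matrix protein of late osteoblasts and osteocytes, fell from 89.8 ± 47.9 to 1.88 ± 1.39 FPKM, and Omd, an osteoblast proteoglycan, from 33.7 ± 9.0 to 3.20 ± 0.065 FPKM. The most abundant members of the osteoblast list, chosen after their values were seen, were Col1a1 (9789 ± 686 and 7435 ± 31.7 FPKM), Col1a2 (4172 ± 356 and 3750 ± 13.1 FPKM), Sparc (2067 ± 41.0 and 1677 ± 70.2 FPKM) and Ibsp (891 ± 299 and 490.3 ± 139 FPKM), with limma adjusted p of 0.117, 0.487, 0.158 and 0.154. Sp7, a transcription factor that acts downstream of Runx2 in osteoblast formation, fell from 45.2 ± 7.74 to 12.1 ± 0.886 FPKM. Genes of muscle and some genes of connective tissue rose. So did Penk, which encodes an enkephalin precursor, from 18.5 ± 0.659 to 143 ± 8.31 FPKM, and Gdf10, a BMP-family ligand, from 28.5 ± 7.66 to 151 ± 1.77 FPKM. Of 11909 genes tested with limma, 274 rose and 165 fell at an adjusted p under 0.05 and a log2 change of at least 1 in size, and 3193 had an unadjusted p under 0.05.

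Leaving out a library changed this count most. Without Runx2_cHet_KO library 1 the same test gave 399 rises and 163 falls, and without Runx2_cHet_KO library 2 it gave 348 and 271. Without Runx2_cHom_KO library 1 limma called 0 genes, with 1570 at an unadjusted p under 0.05, and without Runx2_cHom_KO library 2 it called 1, the small nucleolar RNA Snord61 (listed at 0 in the remaining Runx2_cHom_KO library and chosen after its values were seen), with 1679 at an unadjusted p under 0.05. Each of the 274 rises and 165 falls was therefore lost without Runx2_cHom_KO library 1, and likewise without library 2. Nothing in the labels says that the libraries came from separate embryos, so the p-values measure the spread between these libraries, which may be technical.

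**Figure D3:**
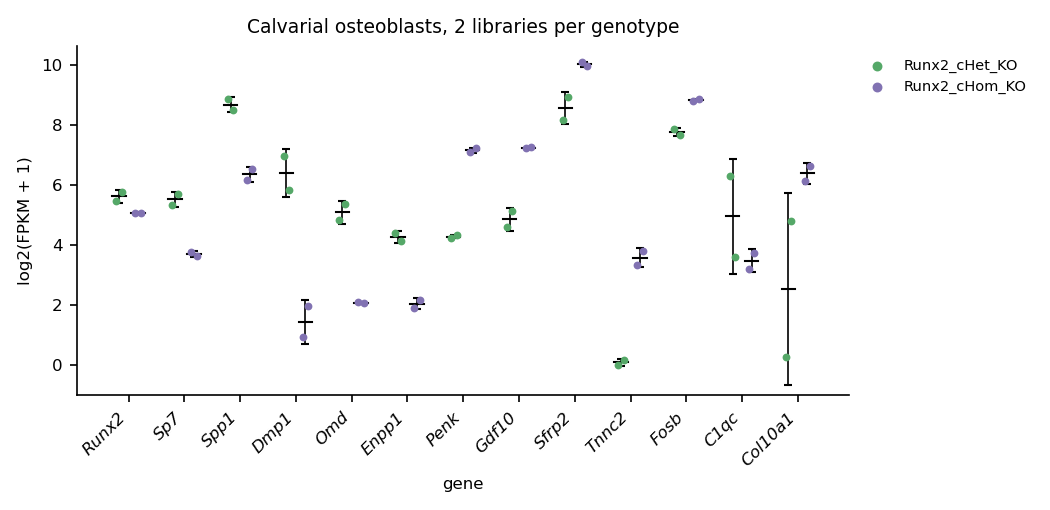
Expression as log2(FPKM + 1) (y axis) of 13 genes (x axis) in 2 Runx2_cHet_KO and 2 Runx2_cHom_KO libraries of calvarial osteoblasts; points are libraries, horizontal lines are means and error bars are SD of the plotted values (n = 2). Sp7, Spp1, Dmp1, Omd and Enpp1 are lower and Penk, Gdf10, Sfrp2, Tnnc2 and Fosb higher in both Runx2_cHom_KO libraries, while C1qc (78.3 and 11.1 FPKM) and Col10a1 (0.202 and 26.9 FPKM) differ widely between the Runx2_cHet_KO libraries.

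Part of the osteoblast list fell. Of 26 measured members of the osteoblast list, 10 fell and 0 rose, or 11 and 0 adjusted over the list alone (median log2 change -0.73, camera adjusted p = 7.50e-10; adjusted p = 0.278 with an estimated correlation). Bglap was at 21.7 and 32.6 FPKM in Runx2_cHet_KO and was listed at 0 in both Runx2_cHom_KO libraries, and Bglap2 was at 24.7 and 22.8 FPKM against a listing at 0 and 0.205 FPKM (adjusted p of 0.00298 and 0.00187); these near-identical genes share reads, so the value of each is uncertain. Among the 12 mineralisation genes 4 fell and 0 rose, or 5 and 0 adjusted over the list alone (median -0.72, adjusted p = 0.000837; adjusted p = 0.362 with an estimated correlation). They were Spp1, Enpp1 (18.3 ± 2.63 to 3.14 ± 0.528 FPKM), Ank (24.3 ± 5.92 to 6.95 ± 1.0 FPKM) and Phospho1, a phosphatase of matrix vesicles (34.9 ± 5.2 to 15.9 ± 2.32 FPKM). The osteocyte list had 1 fall, Dmp1, among 7 members and 0 rises, in both counts, that over all genes and that adjusted over the list alone (median -0.40, adjusted p = 0.263). In the same comparison all 9 measured muscle genes and 3 of 10 endothelial genes rose. Fbln7 (2.07 ± 0.051 and 5.03 ± 1.06 FPKM), Irx5 (30.5 ± 2.73 and 15.5 ± 3.06 FPKM), Phex and Dkk1 of the osteocyte list did not pass both limits.

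The largest falls also held genes outside the lists. Mlip fell from 11 ± 1.70 to 0.584 ± 0.170 FPKM, Npnt, an extracellular matrix protein, from 137 ± 62.4 to 19.1 ± 1.33 FPKM, the citrate transporter Slc13a5 from 28.0 ± 8.36 to 3.45 ± 0.010 FPKM, Anxa8 from 22.9 ± 4.31 to 3.01 ± 0.565 FPKM, and Cgref1 from 56.0 ± 22.0 to 8.34 ± 0.277 FPKM (adjusted p between 0.00662 and 0.0213 for these 5 genes). Among 18 prehypertrophic and hypertrophic genes 4 fell and 0 rose, also when adjusted over the list alone (median -0.56, adjusted p = 0.000224; adjusted p = 0.362 with an estimated correlation). They were Spp1, Sp7, Panx3 (29.0 ± 2.62 to 6.91 ± 2.1 FPKM) and Runx3 (5.96 ± 0.721 to 2.18 ± 0.127 FPKM). Runx3 was the 1 of 4 members of the Runx list that fell, also when adjusted over the list alone (0 rose, median -0.49, adjusted p = 0.00258; adjusted p = 0.362 with an estimated correlation). Runx1 was at 32.0 ± 1.42 and 23.6 ± 0.806 FPKM and Cbfb, the shared partner of the Runx proteins, at 34.6 ± 3.13 and 25.8 ± 0.760 FPKM, with adjusted p of 0.0714 and 0.0912. In the cell cycle list 1 of 21 members, Ccnb1, fell and 0 rose, with the same count adjusted over the list alone, and 20 had negative changes (median -0.68, adjusted p = 1.10e-07; adjusted p = 0.362 with an estimated correlation). Ccnb1 went from 8.35 ± 1.41 to 3.66 ± 0.579 FPKM and its log2 change was -0.98 with centred columns, under the limit; Birc5 (20.4 ± 0.763 and 10.00 ± 0.167 FPKM), Rrm2, Ccna2 and Ccnb2 did not pass both limits.

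Muscle genes rose together. All 9 measured members of the skeletal muscle list rose, also when adjusted over the list alone (0 fell, median 2.23, adjusted p = 1.31e-09; adjusted p = 0.278 with an estimated correlation). The list's median member was at 0.075 and 0.124 FPKM in the Runx2_cHet_KO libraries. Many members thus met the filter of 1 FPKM only through the Runx2_cHom_KO libraries, which favours a shared rise. Acta1 was listed at 0 and at 1.42 FPKM in Runx2_cHet_KO against 19.5 and 22.6 FPKM, a call lost with a pseudocount of 0.1, and Tnnc2 was listed at 0 and at 0.124 FPKM against 9.15 and 12.9 FPKM. Mylpf was at 0.464 ± 0.081 and 8.77 ± 5.30 FPKM and Tnnt3 at 0.702 ± 0.441 and 8.95 ± 2.79 FPKM. The muscle genes Myl1 (0.596 ± 0.135 to 13.9 ± 1.66 FPKM) and Actc1 (0.210 ± 0.074 to 9.73 ± 1.27 FPKM) were also among the 10 largest rises. Of 10 endothelial genes 3 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 1.20, adjusted p = 6.50e-06; adjusted p = 0.419 with an estimated correlation). They were the receptors Tek (1.40 ± 0.079 to 8.56 ± 0.107 FPKM) and Flt1 and the adhesion molecule Esam. The median endothelial gene was 1.96 times as high in Runx2_cHet_KO library 1 as in library 2, with Cdh5, chosen after its values were seen, at 10.4 and 2.17 FPKM there and at 20.6 and 14.7 FPKM in Runx2_cHom_KO. The list median was 1.68 without Runx2_cHet_KO library 1 and 0.83 without library 2. Of 3 epithelial genes 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (median 1.57, adjusted p = 0.00240; adjusted p = 0.362 with an estimated correlation). Krt18 was listed at 0 in both Runx2_cHet_KO libraries and was at 2.43 and 4.64 FPKM in Runx2_cHom_KO, and Epcam went from 0.623 ± 0.307 to 2.59 ± 0.332 FPKM, a call lost with a pseudocount of 0.1.

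Some connective tissue genes rose as well. In the fibroblast, tendon and perichondrium list 3 of 12 members rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.73, adjusted p = 6.65e-05; adjusted p = 0.419 with an estimated correlation). Pi16 went from 3.57 ± 2.22 to 31.6 ± 1.04 FPKM, Thbs4 from 2.44 ± 0.029 to 19.5 ± 5.94 FPKM and Mfap5 from 4.67 ± 0.754 to 25 ± 1.40 FPKM. Clec3b (4.27 ± 3.27 to 50.2 ± 7.89 FPKM), Tnxb (3.15 ± 2.09 to 33.6 ± 0.589 FPKM), Angptl1 (6.80 ± 2.41 to 55.7 ± 5.72 FPKM) and Col6a6 (1.37 ± 0.163 to 15.7 ± 1.75 FPKM) completed the 10 largest rises. Clec3b lost its call with a pseudocount of 0.1. In the columnar cartilage matrix list 1 of 20 members rose, Chad (8.28 ± 3.49 to 31.4 ± 8.72 FPKM), and 0 fell, or 2 and 1 adjusted over the list alone, and 18 had positive changes (median 0.72, adjusted p = 6.65e-05; adjusted p = 0.373 with an estimated correlation). Comp, Cytl1, Col9a2 and 3110079O15Rik of that list, and Col2a1 (115 ± 60.5 and 216 ± 69.3 FPKM, adjusted p = 0.291), did not pass. Col10a1 was at 0.202 and 26.9 FPKM in the Runx2_cHet_KO libraries and at 69.7 and 98.7 FPKM in the Runx2_cHom_KO libraries (log2 change 3.86 with a standard error of 2.14, adjusted p = 0.409).

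Some immediate early genes and a few genes of signalling lists rose. Of 12 immediate early and dissociation-stress genes 5 rose and 0 fell, also when adjusted over the list alone (median 0.79, adjusted p = 1.05e-06; adjusted p = 0.419 with an estimated correlation). Fosb was at 216 ± 19.1 and 457 ± 9.36 FPKM, Fos at 384 ± 0.250 and 820 ± 202 FPKM, Ier2 at 84.1 ± 8.08 and 179 ± 14.8 FPKM, and Jun at 212 ± 51.4 and 443 ± 77.6 FPKM, whose call was lost with centred columns. The other gene that rose, Egr1, was chosen after its values were seen. In the hedgehog list 0 of 12 members passed both limits, or 2 rose and 0 fell adjusted over the list alone, and 11 had positive changes (median 0.69, adjusted p = 0.000693; adjusted p = 0.437 with an estimated correlation). The receptor Ptch1 (25.6 ± 12.3 and 58.4 ± 1.74 FPKM) and the inhibitor Hhip had adjusted p of 0.0973 and 0.165, and Gas1, a co-receptor, was at 24.8 ± 0.818 and 49.2 ± 0.407 FPKM with a log2 change of 0.96, under the limit. In the BMP and TGF-beta list 2 of 19 members rose and 0 fell, also when adjusted over the list alone (median 0.30, adjusted p = 0.000837; adjusted p = 0.437 with an estimated correlation). They were Gdf10 and the BMP antagonist Grem1 (0.479 ± 0.062 to 4.0 ± 1.85 FPKM).

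In the Wnt list genes went both ways, with 4 of 25 rising and 2 falling, or 5 and 2 adjusted over the list alone (median 0.05, adjusted p = 0.230). The median was -0.23 without Runx2_cHet_KO library 1 and -0.021 without Runx2_cHom_KO library 2. Over members at 10 FPKM or more the Wnt list passed upwards (median 0.39, adjusted p = 0.0405), and so did the FGF list (median 0.58, adjusted p = 0.0405). Both calls used the preset correlation. Over all tested members camera gave adjusted p of 0.604 for the Wnt and 0.423 for the FGF list with an estimated correlation. Rspo3 (8.12 ± 1.39 to 30.3 ± 1.32 FPKM) and Rspo2, which enhance Wnt signalling, and Sfrp2, a secreted Wnt-binding protein (391 ± 143 to 1041 ± 63.6 FPKM), rose, and the ligand Wnt10b fell from 5.52 ± 0.976 to 1.39 ± 0.582 FPKM. The remaining calls, a rise of Sostdc1 and a fall of Tcf7, were named after their values were seen. In the FGF list 1 of 12 members rose, Fgf18 (8.19 ± 1.37 to 22.4 ± 0.069 FPKM), and 0 fell, with the same count adjusted over the list alone (median 0.29, adjusted p = 0.123). The FGF list passed the test without Runx2_cHet_KO library 1 (median 0.48), and its median was -0.066 without Runx2_cHom_KO library 1. Spry2, Dusp6, Fgf9 and Etv4 did not pass both limits. Foxc1, a transcription factor of cranial mesenchyme, rose from 15.4 ± 2.55 to 41.7 ± 2.58 FPKM. It was the 1 gene that rose, with 0 falls, among 12 cranial mesenchyme factors (median -0.05 and mean 0.16, adjusted p = 0.230) and among 9 chondrogenic factors (median 0.28, adjusted p = 0.307), with the same counts adjusted over each list alone. Zic1 (31.3 ± 0.410 and 62.9 ± 0.122 FPKM), Alx4, Six2, Pax1, Sox5, Arid5b and Zfp219 did not pass both limits, and Zic1 passed with centred columns or a pseudocount of 0.1. The cranial median lay between 0.0055 and 0.090 without a library. In the protease list 3 of 12 members rose and 1 fell, with the same counts adjusted over the list alone (median 0.23, adjusted p = 0.0770). With the preset correlation the list passed upwards without Runx2_cHet_KO library 1 (median 0.15) and without Runx2_cHom_KO library 2 (median 0.29). With all libraries and an estimated correlation its camera adjusted p was 0.419. Mmp9 went from 2.83 ± 0.524 to 23.8 ± 1.04 FPKM, Adamts1 from 64.8 ± 19.4 to 139 ± 9.60 FPKM, Adamts5 from 7.24 ± 1.19 to 16.5 ± 1.20 FPKM, and Timp1, an inhibitor of matrix metalloproteinases, fell from 78.0 ± 24.7 to 26.7 ± 2.47 FPKM.

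Other lists held few or no calls. In the secretory list 0 of 19 members passed in either count, that over all genes and that adjusted over the list alone (median -0.27, adjusted p = 0.0110; adjusted p = 0.477 with an estimated correlation). The preset call was lost without Runx2_cHet_KO library 1 (median -0.23) or Runx2_cHom_KO library 1 (median -0.26), and over members at 10 FPKM or more (median -0.26, adjusted p = 0.0843). P4hb was at 365 ± 1.44 and 253 ± 14.3 FPKM, and Sdf2l1, Canx and Sec61a1 were also under the limits. Likewise 0 members passed in either count among 17 glycolysis and hypoxia genes (median -0.15, adjusted p = 0.230; Gapdh 341 ± 23.3 and 234 ± 2.62 FPKM, P4ha1 72.4 ± 0.635 and 49.1 ± 0.698 FPKM, Eno1, Ankrd37) and among 14 cholesterol genes (median -0.17, adjusted p = 0.286; Fdps, Lss, Sqle). This was also so for 4 adipocyte genes (median 0.75, adjusted p = 0.128; Fabp4, Pparg, Lpl, Cebpa), a list that passed upwards without Runx2_cHet_KO library 1 (median 1.22). It was so too for 4 neural and Schwann genes (median 0.42 with a mean of 0.25, adjusted p = 0.230; Sox10, Tubb3, S100b, Stmn2). Of 5 osteoclast genes Mmp9 alone rose and 0 fell, also when adjusted over the list alone (median 0.39, adjusted p = 0.101), while Ctsk (90.7 ± 1.33 and 80.9 ± 4.55 FPKM), Acp5, Nfatc1 and Itgb3 did not pass. The osteoclast list passed upwards with the preset correlation without Runx2_cHom_KO library 2 (median 0.56). With all libraries and an estimated correlation its camera adjusted p was 0.448.

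Macrophage genes were highest in 1 osteoblast library, and red-cell genes in library 1 of each genotype. Of 11 macrophage genes 0 passed in either count, over all genes or adjusted over the list alone (median -0.96, adjusted p = 0.0903). C1qc was at 78.3 FPKM in Runx2_cHet_KO library 1, at 11.1 FPKM in Runx2_cHet_KO library 2 and at 8.18 and 12.4 FPKM in the Runx2_cHom_KO libraries, and Ctss, C1qa and Fcer1g were likewise highest in Runx2_cHet_KO library 1, with 31.8, 55.2 and 52.1 FPKM against 5.08, 7.12 and 5.99 FPKM in library 2. The median macrophage gene was 7.13 times as high in Runx2_cHet_KO library 1 as in library 2, and without library 1 the list median turned to 0.38 and the list passed the test upwards. Without Runx2_cHet_KO library 2 it was -2.22 and the list passed downwards. Of the erythroid list only Alas2 was measured (11.1, 2.24, 9.33 and 2.49 FPKM in Runx2_cHet_KO libraries 1 and 2 and Runx2_cHom_KO libraries 1 and 2), which is under the 3 members a list test needed, and 0 neutrophil genes were measured. The merged alpha-globin row was at 556, 25, 462 and 133 FPKM and the row Beta-s at 459, 25.8, 454 and 160 FPKM in the same order. Of 26 lists tested, 8 had higher and 6 lower calls with the preset correlation and 0 had a call with an estimated one. List calls with a library left out were made with the preset correlation only.

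**Figure D4:**
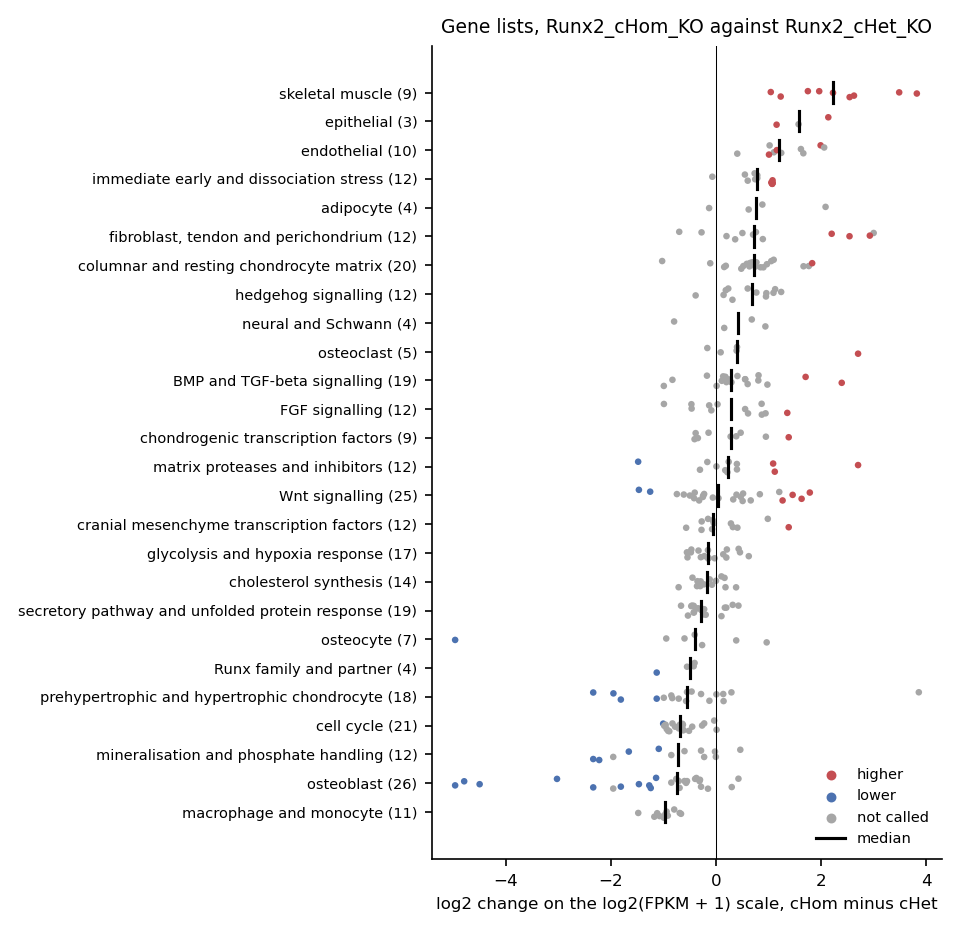
Log2 change (x axis, log2(FPKM + 1) scale, Runx2_cHom_KO minus Runx2_cHet_KO) of each member of 26 gene lists (y axis, with the number of members tested); points are genes, coloured where they passed the limma test upwards (red) or downwards (blue), and black bars are list medians. All 9 muscle genes are coloured red, 10 of 26 osteoblast genes blue, and the 11 macrophage genes, which differ between the Runx2_cHet_KO libraries, are uncoloured.

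The last comparison asked whether genes that differed between the rib sorts also differed between the genotypes. The 2 sets of libraries came from different kits, strains and ages, and each table was analysed alone. Of 7758 genes above the floor in both tables, 35 were higher in Col10+ cells and fell in Runx2_cHom_KO, beside 10.8 for independent lists of these sizes. They included Bglap and Bglap2, the transporter Slc13a5 (0.328 and 11.1 FPKM in the sorts), Glipr1 (1.16 and 15.1 FPKM; 7.95 and 0.904 FPKM in the genotypes, with its call lost at a pseudocount of 0.1) and the collagen Col22a1 (0.386 and 24.0 FPKM; 32.4 and 5.89 FPKM). In the opposite pair, 39 genes were lower in Col10+ cells and rose in Runx2_cHom_KO, beside 13.8. Among them were Penk (277 and 43.6 FPKM in the sorts), Krt18 and Angptl1. Dlk1, an inhibitor of adipocyte differentiation (778 and 106 FPKM in the sorts, 32.5 and 181 FPKM in the genotypes), and Sema3c (24.5 and 4.04 FPKM, 32.3 and 105 FPKM) were others. All 5 immediate early genes that rose in Runx2_cHom_KO, Fos, Fosb, Jun, Egr1 and Ier2, were also among these 39. What share of the overlap such genes make up was not tested.

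Genes with the same direction in both comparisons were also counted. Higher in Col10+ cells and risen in Runx2_cHom_KO were 28 genes, beside 11.5. At the top were Clec3b, Mmp9, Thbs4, Emilin2 (4.36 and 39.4 FPKM in the sorts, 5.87 and 25.7 FPKM in the genotypes) and Col5a3 (2.83 and 11.9 FPKM, 11.3 and 40.1 FPKM). The muscle genes Acta1 and Tnnt3 and the endothelial gene Esam were also among these 28. Lower in Col10+ cells and fallen in Runx2_cHom_KO were 19 genes, beside 13, led by Enpp1 and Ank. Next came Cd109 (230 and 73.4 FPKM in the sorts, 32.6 and 10.1 FPKM in the genotypes). The cell cycle inhibitors Cdkn1a (427 and 100 FPKM, 127 and 47.8 FPKM) and Cdkn2b (14.1 and 2.79 FPKM, 2.15 and 0.211 FPKM) followed. Spp1, named after its values were seen, was also in this overlap (3400 and 1614 FPKM, 413 and 81.2 FPKM). At the 1.5-fold limit that last overlap was 66, beside 88.2, and without Runx2_cHet_KO library 2 it was 23, beside 27.0, so it lay below the value for independent lists in both cases. Without Runx2_cHet_KO library 2 the genes higher in Col10+ cells and fallen numbered 116, beside 22.2. Without Runx2_cHet_KO library 1 those higher and risen numbered 60, beside 20.3, and those lower and risen 59, beside 25.5. In the fit without Runx2_cHet_KO library 2 the macrophage list median was -2.22, and in the Col10+ sort it was 6.95. Macrophage genes can thus enter the overlap of higher and fallen genes in that fit, and their share of it was not counted. No p-value is given, because the chondrocyte values have no replicates and genes are not independent. Without Runx2_cHom_KO library 1, and likewise without library 2, each of the 4 overlaps was 0, since the osteoblast calls were lost.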

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

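The tests in this part were chosen after the results were seen, except that the gene lists for blood, muscle and endothelial cells were fixed before the data were examined. Rows of the chondrocyte table without a gene name, which no comparison used, held 17.05% of the summed FPKM of the Col10+ sort and 8.48% of the Col2+ sort. The rRNA precursor row Rn45s, at 614 and 24995 FPKM, and the row Tomm70a, at 9074 and 180010 FPKM, were also far higher in the Col10+ sort. So was the row Lars2, at 430 and 8819 FPKM. In the osteoblast libraries Tomm70a was at 10.00 to 14.7 FPKM and Lars2 at 838 to 1312 FPKM. The 2 sorts thus differed widely in these abundant rows, and the cause was not tested. Of the summed 712295 FPKM of the Col10+ sort 180010 stood in the Tomm70a row, and whether that row measures Tomm70a transcripts is uncertain without the reads.

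Genes of neutrophils, macrophages and red cells were far higher in the Col10+ sort. The tables argue against scaling of the 2 columns, because the median log2 change of neutrophil and macrophage members was 7.13 after centring, with a lower quartile of 5.19. Of the 23 measured members of the neutrophil, macrophage and erythroid lists 95.7% were higher, led by S100a9 at 1929 FPKM and S100a8 at 971 FPKM, and 0 belong to another of the lists; this share restates the pattern and tests no source. Blood cells in the Col10+ sort, which the mCherry gate on the Col10a1 reporter would be meant to remove, and expression by the Col10+ chondrocytes themselves cannot be told apart, since the table holds 1 value per sort and none per cell.

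All 9 measured muscle genes and 3 of 10 endothelial genes rose in Runx2_cHom_KO. A lower share of osteoblasts would raise the markers of every other cell type alike. Over the fit of all 4 libraries and the 4 fits without a library the macrophage median reached at most 0.38. This lay below 1.75, the lowest of the lower quartiles of the muscle members. Many muscle members met the filter of 1 FPKM only through the Runx2_cHom_KO libraries, which favours a high quartile. Fits with Runx2_cHet_KO library 1 cannot test an equal rise, because its median macrophage gene was 7.13 times as high as in library 2. The 0.38 came without it, from the lone other library of that genotype. Over all 4 libraries the endothelial, epithelial, fibroblast, adipocyte, neural and osteoclast medians were 1.20, 1.57, 0.73, 0.75, 0.42 and 0.39. A lower share therefore stays open as a part of the rise. All 19 measured muscle and endothelial members, 100%, had positive changes, which restates the pattern and tests no source. More muscle and vessel cells in these preparations and a difference brought by the genotype both stay open as untested; Acta1, at 19.5 and 22.6 FPKM, was the most abundant muscle gene named here, and the labels do not say how the calvaria were dissected.

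With the genotypes, limma called 439 genes. The 4 libraries can be split into equal pairs in 3 ways, too few for a share under 0.05; 1 of these splits, the genotypes, gave as many calls, and the highest of the others gave 4.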

How the results depend on the processing

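Leaving libraries out of the named genes, lists and overlaps, and the block for genes and lists, were chosen after seeing the data; the cause of a change was not tested unless stated. In the chondrocytes, higher calls were 1940 with no filter, 731 at 10 FPKM or more and 659 at 4-fold, beside 1150, and lower calls were 699 with a pseudocount of 5, 2773 at 1.5-fold, 181 at 4-fold and 606 with centred columns or with equal totals, beside 1188. In the osteoblasts, rises and falls were 106 and 51 with a pseudocount of 5, 153 and 95 with no filter, 131 and 86 at 10 FPKM, 434 and 380 at 1.5-fold and 35 and 17 at 4-fold. Fold limits change the counts of both comparisons by construction, and so do filters in the chondrocytes, which had no test. Why the osteoblast counts were lower with no filter was not tested. Leaving out a library gave 0 to 399 rises and 0 to 271 falls. The lone library of a group is then assumed to vary like the pair of the other, and the pairs differed: 3.06% of genes were at least 2-fold apart in the Runx2_cHet_KO pair and 1.09% in the Runx2_cHom_KO pair.

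With the replicate block 174 genes rose and 119 fell. Of the named osteoblast genes 16 had a call without the block and none with it, and 3 gained one. The macrophage list then passed downwards (adjusted p = 0.0220) and the adipocyte list upwards (adjusted p = 0.0227). The deviations of same-numbered libraries correlated at -0.05 over all genes tested, and the labels do not say what a number marks, so the numbers were not taken to pair the libraries; the alpha-globin row, Beta-s and Alas2 were nonetheless higher in library 1 than in library 2 of both genotypes. No paired analysis was possible for the chondrocytes because their columns are group values. List calls in the osteoblasts went from 8 higher and 6 lower to 0 and 0 with an estimated correlation. This setting also takes its degrees of freedom from the few libraries, so the loss does not show that correlation between genes removed the calls. The osteoblast and skeletal muscle lists had estimated correlations of -0.032 and -0.110, below the preset 0.01. Overlaps at 1.5-fold were 61 (higher, risen), 99 (higher, fallen), 93 (lower, risen) and 66 (lower, fallen), beside 35.4, 44.3, 70.4 and 88.2 for independent lists, so the last lay below that value. At 10 FPKM they were 17 (higher, risen), 13 (higher, fallen) and 9 (lower, fallen), beside 4.99, 3.60 and 6.43. Without a library they ranged from 0 to 60, 116, 59 and 23.

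Signs of list medians and named genes turned in these cases. With centred columns the chondrocyte medians of the mineralisation, Runx, Wnt and secretory lists went from -0.06, -0.16, -0.10 and -0.29 to 0.19, 0.17, 0.23 and 0.05. The chondrocyte protease median was -0.52 at 10 FPKM, and the osteoblast chondrogenic factor median -0.14 at 10 FPKM (0.13 to 0.43 without a library). Without a library the osteoblast medians ranged from -2.22 to 0.38 for macrophage, 0.0055 to 0.090 for cranial mesenchyme, -0.23 to 0.25 for Wnt and -0.066 to 0.57 for FGF genes, and uncalled genes from -1.01 to 0.89 (Alas2), -2.39 to 0.045 (Ctss), -2.51 to 0.28 (C1qa), -2.53 to 0.39 (Fcer1g), -0.41 to 0.59 (Acp5), -0.0056 to 0.32 (Stmn2), -0.047 to 1.29 (Lpl) and -0.40 to 0.14 (Cebpa). With centred columns 4 named chondrocyte genes lost and 1 gained a call, and 2 osteoblast genes lost and 1 gained one; a pseudocount of 0.1 ended 4 and added 5 osteoblast calls. Unknown depth leaves the counting error of low genes unmeasured.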

Other observations

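All tests here were chosen after the data had been examined, on lists written after they were noticed, and the genes named were chosen after their values were seen. Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were lower in the Col10+ sort in 22 of 25 measured cases and higher in 0 (median log2 change -2.06, percentile 0). In the same sort the immediate early and dissociation stress genes had a median of -2.51, and the neutrophil and macrophage genes medians of 7.08 and 6.95. Asns, asparagine synthetase, was at 246 FPKM in Col2+ and 42.4 FPKM in Col10+ cells, Psat1 and Phgdh, enzymes of serine synthesis, at 158 and 20.3 FPKM and at 152 and 18.6 FPKM, and the amino acid transporter Slc7a5 at 213 and 27.9 FPKM. In the osteoblasts 4 of 20 fell and 0 rose (median -0.46, camera adjusted p = 0.000268 from a limma fit with a preset correlation, adjusted p = 0.407 with an estimated correlation, both over 29 lists): Asns, Psat1, Mthfd2 and Sesn2.

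Some imprinted genes differed in each table. In the Col10+ sort 9 of 22 were lower and 0 higher (median -0.82, percentile 0.14), among them Dlk1, H19 (1588 and 738 FPKM) and Igf2r (97.2 and 41.5 FPKM). In Runx2_cHom_KO osteoblasts 5 of 20 rose and 0 fell (median 0.68, camera adjusted p = 6.42e-08 from a limma fit with a preset correlation, adjusted p = 0.349 with an estimated correlation), namely Dlk1, Plagl1, the cell cycle inhibitor Cdkn1c, Rtl1 and Nnat. H19 was at 2574 and 3142 FPKM in Runx2_cHet_KO and 2940 and 2809 FPKM in Runx2_cHom_KO. In these osteoblasts all 9 measured muscle genes also rose (median 2.23). In the Col10+ sort the neutrophil and macrophage genes had medians of 7.08 and 6.95.

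Of 32 measured targets of the tumour suppressor p53, on a list that includes the genes that prompted it, 18 fell and 0 rose in Runx2_cHom_KO osteoblasts (median -1.11, camera adjusted p = 1.32e-13 from a limma fit with a preset correlation, adjusted p = 0.207 with an estimated correlation), among them Ccng1 (48.2 and 47.1 against 17.2 and 20.4 FPKM), Eda2r (11.4 and 12.5 against 2.85 and 3.15 FPKM) and Phlda3 (46.4 and 48.2 against 17.4 and 18.9 FPKM); in the Col10+ sort 5 of 31 were lower and 3 higher (median -0.11, percentile 60.3). The tables argue against macrophages in Runx2_cHet_KO library 1 as the source, because the median was -1.15 (SD of members 0.642) without that library. Dilution of osteoblast RNA by other cells stays open. The 10 most abundant osteoblast-list genes had a median of -0.35, with an SD of 0.894 that is a spread between genes. Col1a1 and Sparc changed by -0.39 and -0.30, less than the p53 median, and Spp1 and Smpd3 by -2.33 and -1.95, more than it. Such unequal changes give no single dilution factor to set against the p53 median. A difference in p53 targets that goes with genotype remains a hypothesis: the 18 members not used to notice the pattern had a median of -0.70, with 5 falls and 0 rises (camera p = 2.91e-05 from a limma fit, p = 0.0716 with an estimated correlation, both unadjusted). The pattern may extend to them, but their set call was lost with the estimated correlation, and the gene calls were lost without a Runx2_cHom_KO library.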
